A study of Homo sapiens with 4 samples.

How the data were processed

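The data were enhanced crosslinking and immunoprecipitation (eCLIP) libraries of ADAR, the adenosine deaminase that edits double-stranded RNA, from K562 cells, a human chronic myeloid leukaemia line with erythroid features. There were 2 immunoprecipitated (IP) libraries made with an antibody against ADAR1 and 2 input libraries, numbered as replicates 1 and 2. Per the labels' protocols, cells were crosslinked with 254 nm ultraviolet light at 400 mJ/cm2, RNA was trimmed with RNase I, and RNA was recovered from a gel region 75 kDa above the protein. Nothing in the labels says that the replicates came from separate cultures, so differences between them may be technical.

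Per the submitters' processing notes, cutadapt 1.9 and STAR 2.4.0i were used, and several genome builds were named. The peak caller is not given in the sources used here. The coordinates fit GRCh38, because clusters on chromosomes 17, 20 and X reached 83224967, 64307486 and 156025223, beyond the ends of those chromosomes in the older build.

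The authors deposited 3 peak lists: the clusters of each replicate, and a list that combines the replicates, called here the reproducible list. The −log10 p-values in the deposited lists are the authors' significance of IP over input, limited to 400. The log2 fold values in the deposited lists are the authors' IP over input, scaled to library totals as far as the values show. These are values of the authors' deposited lists and are used to describe, rank and filter peaks. How the authors combined the replicates is not given in the sources used here. In the reproducible list, 786 intervals were identical to a replicate 1 cluster and 937 to a replicate 2 cluster. For the 9 intervals identical to a cluster in both, the log2 fold was the mean of both values within a tolerance of 1e-06. Whether it is a mean for the other intervals was not tested.

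A cluster was called enriched at a log2 fold of at least 3 and a −log10 p of at least 3. Host genes were taken from RefSeq gene spans of GRCh38.p14 by the cluster midpoint. The annotation used here held gene spans without strands or exons. Gene strand was therefore taken from the clusters themselves, where at least 5 clusters lay in a gene alone and at least 80% shared a strand. Where spans overlapped, small RNA genes of up to 400 bases were preferred, then protein-coding genes, then long noncoding RNA genes. Intron, exon and untranslated region were not assigned, and coordinates are given from 1.

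The number of reads per library is not stated, but the depth of IP relative to input could be recovered. The log2 folds of each replicate were log2 ratios of whole numbers plus a constant. With denominators up to 200 and a tolerance of 1e-07, 99.9% of replicate 1 values and 99.7% of replicate 2 values fell on such steps, against 0.326% and 0.157% on a shifted scale. The constant was set by taking the commonest fold as 3 IP reads over 1 input read. Under that assumption an exact binomial test matched the authors' p within 0.02 for 93.7% of the replicate 1 clusters and 90.9% of the replicate 2 clusters examined. Those examined were the 140633 and 121770 clusters in the 200 commonest pairs of fold and p of each replicate. Other assumptions matched at most 14.6% of them. Over all clusters on the steps with a p in the range tried, the matched share was 85.3% in replicate 1 and 84.8% in replicate 2. IP depth was 3.33 times input in replicate 1 and 0.553 times input in replicate 2. Denominators are those of the ratio in lowest terms, so the input reads were that number or a multiple of it. The step of 1 input read thus holds clusters at 1 input read and some with more. Minimums of input reads, used below, were set on these denominators. They leave out well-covered clusters whose ratio reduces to a smaller denominator.

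The share of enriched peaks overlapped by the other replicate (at least 1 base, same strand) has an exact 95% binomial interval, which covers counting error only and treats peaks as independent. It was compared with 1000 random placements of the other replicate's peaks inside their genes, one-sided. Clusters were paired by mutual best overlap, and their folds were correlated across clusters with 100000 two-sided permutations. Clusters are not independent replicates.

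There were 13 gene lists fixed before the data were examined. They were edited or recoding targets, transcripts with inverted Alu repeats in the 3′ untranslated region, double-stranded RNA sensors and interferon genes, double-stranded RNA binding proteins, zinc finger genes, erythroid genes, hepatocyte genes, ribosomal protein genes, histone genes, nuclear long noncoding RNAs, abundant small noncoding RNAs, microRNA genes with their hosts, and mitochondrial genes. Lists were written from general knowledge, and their members were not checked. Each was compared with 10000 random lists matched in 20 bins of clusters per gene, which permutes list membership within bins, two-sided, with Benjamini-Hochberg adjustment over the 13 lists, and called at an adjusted p under 0.05. Genes with any cluster in either replicate formed the background. The same background and bins served the tests of a single replicate. On simulated data, 2.7% of random lists had unadjusted p under 0.05. Of simulated lists of 30 genes with a peak chance raised 3-fold, 30% had unadjusted p under 0.05, and at 6-fold 78% did. The adjusted call used here is stricter, so small lists could miss a moderate excess more often than these shares show. The overlap search gave the direct search's answer for 400 of 400 peaks. Of 100 simulated lists without an effect, 2 had p under 0.05. They were placed in the same way as their background, so this checks the computation only.

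Named genes were the 12 genes with the most reproducible peaks (ties by the highest log2 fold), the genes of the 10 reproducible peaks with the highest log2 fold, and up to 4 genes per list with the most reproducible peaks, ties broken likewise. A gene that this rule named is not reported here. The thresholds, lists, tests and this rule were set before the data were examined. There were 8 added analyses, chosen after seeing the data: the read steps, host gene classes, position in the gene, genes enriched in both replicates, mitochondrial strands, small RNA classes, the top genes of each replicate, and chromosome 22. For host classes and position, the background was clusters of both replicates together that were not enriched and overlapped no enriched or reproducible peak. Genes were resampled 500 times. Replicate 1 had more clusters than replicate 2, so a comparison of 1 replicate's peaks with this background may also reflect differences between the replicates. A further 2 tests of the closing section were changed after a first value was seen, and both versions are given there. The planned comparisons of gene regions, Alu overlap and folding energy were not run, because no genome sequence or exon annotation was used here. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.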

Results

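ADAR-bound RNA was mapped in K562 cells from 2 IP libraries and 2 input libraries. ADAR deaminates adenosine to inosine in double-stranded RNA, and the series concerns the prediction of protein binding sites on RNA. Replicate 1 held 534161 clusters with a median width of 47 bases, and replicate 2 held 155848 clusters with a median width of 59 bases. The reproducible list held 1717 peaks in 539 genes. Touching peaks merged into 945 sites. All fold values are the authors', per peak, as log2 of IP over input.

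The gene with the most reproducible peaks was MIR17HG, the host transcript of the miR-17-92 microRNA cluster, with 25 peaks on chromosome 13 between 91347956 and 91349184. It was followed by CDC45, a replication helicase factor, with 24 peaks on chromosome 22 between 19500161 and 19505099. GOLGA4, a golgin of the trans-Golgi, held 23 peaks and LARP4B, an RNA-binding protein, held 16. MED13, a subunit of the Mediator kinase module, held 13, while RRM2, the small subunit of ribonucleotide reductase, and XPO1, the nuclear export receptor, held 12 each. The RRM2 peaks lay between 10160795 and 10164270 in a gene span of 10122568 to 10211010. Exons were not assigned, so these peaks are not shown to lie in the reductase messenger RNA. P4HA1, LOC440910, LARS1, RCOR1 and PPP6R3 had the highest folds among 10 genes tied at 10 peaks. These 12 genes, of 17 with 10 or more peaks, held 175 of the 1717 peaks (10.2%), while 151 genes held 1 peak and 92 held 5 or more.

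The replicates contributed unequally to several of these genes. MIR17HG had 39 enriched peaks among 40 clusters in replicate 1 and 0 among 10 clusters in replicate 2, where its highest log2 fold was 2.96. Its reproducible peaks therefore rest on replicate 1 for passing log2 fold 3. CDC45 had 28 enriched peaks in replicate 1 and 33 in replicate 2, and GOLGA4 had 25 and 27. XPO1 had 4 and 31, and MED13 had 6 and 26. Of the 1717 reproducible peaks, 1378 overlapped an enriched peak in both replicates, 1427 in replicate 1 and 1665 in replicate 2. Neighbouring peaks of a gene are not independent. Leaving out spans called to the opposite strand, 139 peaks lay in more than 1 gene span.

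**Figure D1:**
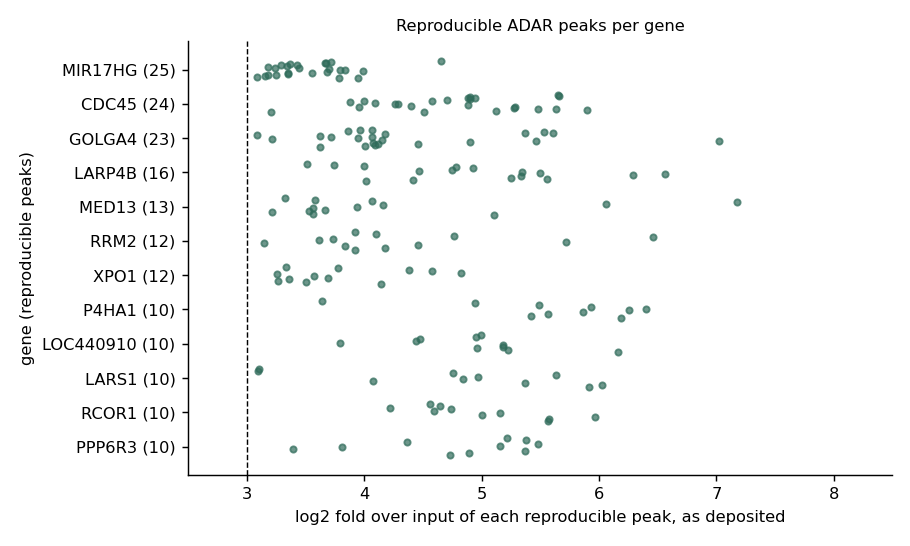
Log2 fold over input (horizontal axis) of each reproducible peak in the 12 genes with the most peaks (vertical axis, number of peaks in parentheses); each point is 1 peak and the dashed line marks log2 3. The MIR17HG peaks lay between 3.08 and 4.66, and the highest point was in MED13 at 7.18.

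Among the genes with the highest folds, JARID2, a cofactor of Polycomb repressive complexes, reached log2 7.77 at chromosome 6 positions 15307210 to 15307231 on the plus strand. HAT1, a histone acetyltransferase, had 1 reproducible peak at 7.23 on chromosome 2, positions 171949293 to 171949361. MED13 reached 7.18 on chromosome 17, and DLEU2, a long noncoding RNA, reached 7.12 on chromosome 13. Among the 10 highest peaks, 2 lay in no annotated gene, at chromosome 9 positions 65388038 to 65388094 (log2 7.59) and 65388095 to 65388152 (log2 7.54). They belonged to a group of 21 peaks between 65385728 and 65390640, out of 80 reproducible peaks in no annotated gene. Across the list the median log2 fold was 4.62. The highest cluster of DLEU2 had log2 5.84 in replicate 1 and 8.41 in replicate 2, while that of JARID2 had 7.63 and 7.92.

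The first comparison was between IP and input within each replicate. GSE1 led replicate 1 with 127 enriched peaks against 40 in replicate 2. CBFA2T3, a transcriptional corepressor, had 79 against 2, and ZFPM1, the erythroid cofactor FOG1, had 70 against 0. ACTB and PTMA each had 34 enriched peaks in replicate 1 and 0 in replicate 2. UBE2K, a ubiquitin-conjugating enzyme, led replicate 2 with 46 against 10 in replicate 1, and CUX1 had 43 against 5. These genes were chosen after their values were seen, apart from genes named above. Replicate 1 had 7408 enriched peaks (1.39% of its clusters) in 2286 genes, and replicate 2 had 19992 (12.8%) in 4655 genes. The median log2 fold over all clusters was 0.07 in replicate 1 and 1.85 in replicate 2. IP depth relative to input was 6.01 times higher in replicate 1, and at 1 input read an enriched call, decided there by the p threshold, needed 37 IP reads in replicate 1 and 9 in replicate 2. Of the enriched peaks, 66.6% in replicate 1 and 56.3% in replicate 2 had a ratio with a denominator of 1 in lowest terms. These shares include peaks with more than 1 input read. They are upper bounds for peaks at 1 input read, where the fold has little precision. Each list gives 1 value per peak, so no test between the replicates was made for a gene.

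**Figure D2:**
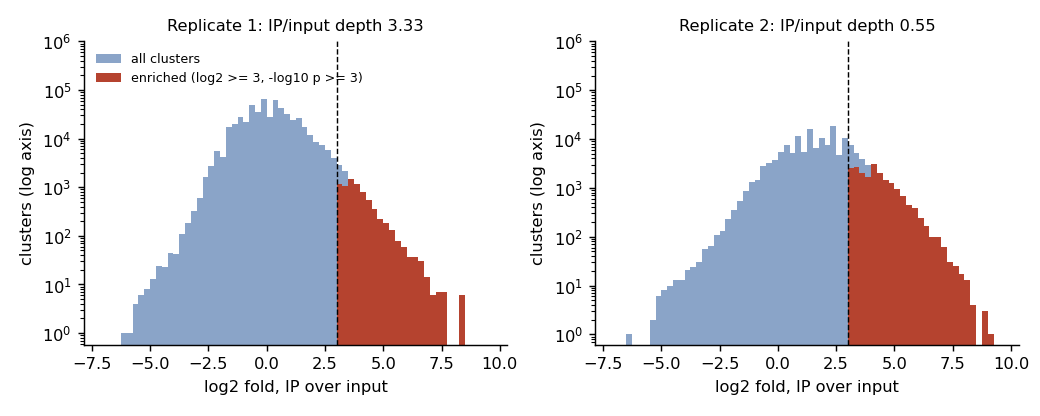
Number of clusters (vertical log axis) by log2 fold of IP over input (horizontal axis) in replicate 1 (left) and replicate 2 (right); red bars are enriched clusters and the dashed line marks log2 3. Enriched clusters numbered 7408 on the left and 19992 on the right.

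The second comparison was between replicates. GOLGA4, CDC45, RRM2 and JARID2 had enriched peaks in both, and 1670 genes had an enriched peak in each replicate. Random genes matched on clusters per gene gave a mean of 1407 (central 95% 1377 to 1436; permutation p = 0.0002, the smallest that 10000 draws can give). Of the replicate 1 enriched peaks, 41.9% (95% interval 40.8 to 43.0) were overlapped by an enriched peak of replicate 2. In the other direction, 2798 of the 19992 replicate 2 enriched peaks (95% interval 13.5% to 14.5%) were overlapped by replicate 1. Random placement inside genes gave means of 1.47% and 0.550%, with permutation p = 0.000999 in both directions, the smallest that 1000 placements can give. Random draws of clusters from the same gene, a stricter background chosen after seeing the data, gave 15.6% and 3.30%. When any cluster of the other replicate counted, the shares were 64.0% and 88.4%.

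Across 87894 paired clusters, the log2 folds of the replicates had Pearson's r = 0.52 and Spearman's rho = 0.48 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). The correlation is across clusters, which are not independent. Over all pairs the median fold was higher in replicate 2 by 1.36 on the log2 scale. This difference depended on the minimum set for the denominators, in lowest terms, in both replicates. It was 0.74 with at least 5, 0.21 with at least 10 and −0.12 with at least 15 (95% gene-resampled interval −0.22 to 0.00). These minimums were chosen after seeing the data, and they leave out pairs with as many input reads whose ratio reduces. Among the pairs, 2145 were enriched in both replicates, 1244 in replicate 1 and not 2, and 13233 in replicate 2 and not 1.

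The third comparison asked whether gene groups held more reproducible peaks than matched genes. Mitochondrial genes did, with 8 of 25 genes against a random mean of 0.28 (adjusted permutation p = 0.0026). Their leading members were ND6, a complex I subunit, with 8 peaks of log2 3.55 to 4.91, TRNF with 5, COX1 with 4 and ND1 with 2. All peaks of ND6, TRNF, TRNR and TRNY overlapped an enriched peak in both replicates, as did 1 of the 4 in COX1 and 1 of the 2 in ND1. The peaks of CYTB and TRNI, 1 each, did not. Random genes were matched on clusters per gene and not on read depth, so an excess over genes of like depth was not tested. Replicate 2 alone also gave 8 of 25, without passing the test (adjusted permutation p = 0.12), while replicate 1 alone gave 12 of 25 (adjusted permutation p = 0.00087).

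No other list passed the test on the reproducible peaks. Known edited or recoded transcripts had peaks in 4 of 26 genes (adjusted permutation p = 0.49): MFN1, a mitochondrial fusion GTPase, with 5 peaks up to log2 6.07, NARF with 3, SON with 2 and H2AC21 with 1. Among erythroid genes 5 of 37 had peaks (adjusted permutation p = 0.49), led by TFRC, the transferrin receptor, with 5 peaks, EPB41 with 4 and ANK1 with 2. Transcripts with inverted Alu repeats in the 3′ untranslated region had peaks in 3 of 30 genes (adjusted permutation p = 0.49): SPN with 4, MDM2 with 3 peaks up to log2 6.58 and VHL with 1. The list named double-stranded RNA binding proteins had peaks in 2 of 29 genes (adjusted permutation p = 1), HNRNPC with 3 and SON with 2. Whether each member, HNRNPC included, binds double-stranded RNA was not checked. Double-stranded RNA sensors and interferon genes had 0 of 21 (adjusted permutation p = 1).

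Zinc finger genes had peaks in 12 of 447 (adjusted permutation p = 1), among them ZNF562 with 4 and ZNF316 and ZNF124 with 3 each. Ribosomal protein genes had peaks in 3 of 83 (adjusted permutation p = 0.49): RPS3A with 5, RPL37A with 4 and RPSA with 2. Histone genes had 2 of 59 (adjusted permutation p = 0.295), H4C15 with 4 peaks and H2AC21 with 1. The H4C15 peaks lay between 149850111 and 149850323 in a gene span of 149844488 to 149861240. Leaving out spans called to the opposite strand, 1 other gene span held the top peak. Exons were not assigned, so these peaks are not shown to lie in the histone transcript. Nuclear long noncoding RNAs had 2 of 19, DLEU2 and CYTOR (adjusted permutation p = 1). MicroRNA genes and hosts had 4 of 393 (adjusted permutation p = 0.49), MIR17HG, MIR378A, MIR1304 and MIR3686. For the last 3, no strand could be set, and 1 other gene span also held the top peak. Small RNA genes were preferred there, so these peaks are not shown to lie in the microRNA transcripts. Abundant small noncoding RNAs had 0 of 20 and hepatocyte genes, a group of another cell type, had 0 of 5 with a cluster (adjusted permutation p = 1 for each). A missed threshold does not show that a group lacks an excess.

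Some lists passed within a single replicate. In replicate 1, microRNA genes had 65 of 393 (random mean 12.5), ribosomal protein genes 34 of 83 (random mean 8.61) and histone genes 7 of 59 (random mean 2.4), with adjusted permutation p = 0.00087, 0.00087 and 0.047. In replicate 2, microRNA genes had 29 of 393 (random mean 14.9, adjusted permutation p = 0.0026), while ribosomal protein genes had 23 of 83 (adjusted permutation p = 0.54) and histone genes 4 of 59 (adjusted permutation p = 1). Whether the replicates differed in these lists was not tested. Background and matching used the clusters of both replicates together. A gene without a cluster in the replicate tested therefore counted as a gene without a peak. Replicate 2 had clusters in 11868 of the 17490 background genes. Matching did not cover read depth, so an excess over genes of like depth was not tested for these lists either.

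**Figure D3:**
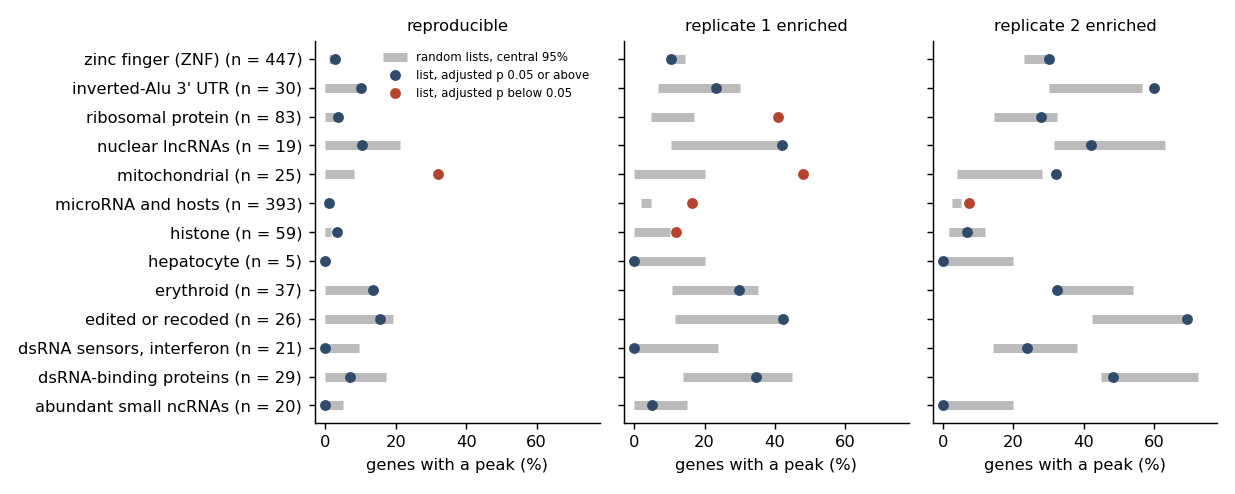
Percent of each list's genes with a peak (horizontal axis) for the reproducible list, replicate 1 and replicate 2; grey bars are the central 95% of random lists matched on clusters per gene, and red points have adjusted p under 0.05. On the reproducible list the mitochondrial genes were the red point, at 32.0%.

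Mitochondrial clusters were examined by strand after seeing the data. Minus-strand clusters, in the orientation of ND6 and of transcripts from the light-strand promoter, were enriched in 13 of 13 cases in replicate 1 and 10 of 12 in replicate 2. Most of them lay in ND6, where 10 of 10 were enriched in replicate 1 and 9 of 9 in replicate 2. Outside ND6, TRNY was enriched in both replicates, while the lowest minus-strand log2 fold in replicate 2 was 0.64. The pattern thus rests largely on 1 gene. Plus-strand clusters were enriched in 12 of 223 and 21 of 162. Fisher's exact test gave two-sided p = 6.44e-15 and 4.24e-07, but neighbouring clusters touch, so these p-values are too small. ND6 held its reproducible peaks between positions 14256 and 14507, TRNF between 586 and 643, and TRNR had 1 peak at log2 5.65. TRNY, also on the minus strand, had 1 at 4.35.

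**Figure D4:**
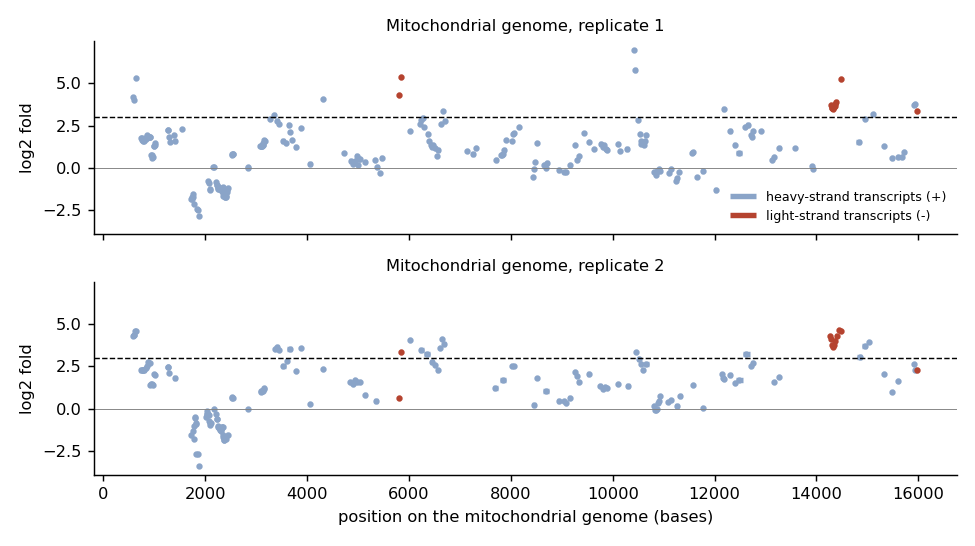
Log2 fold of IP over input (vertical axis) of clusters along the mitochondrial genome (horizontal axis, bases) in replicate 1 (top) and replicate 2 (bottom); red marks are minus-strand clusters, blue marks plus-strand clusters, and the dashed line marks log2 3. The red group near the right holds the ND6 peaks between positions 14256 and 14507.

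Host classes and positions were also compared after seeing the data. Mitochondrial genes held 1.34% of reproducible peaks against 0.0504% of background clusters, and small RNA and other genes held 0.990% against 0.370%, with gene-resampled intervals of the difference above 0. The replicates did not share this: small RNA and other genes held 1.93% of replicate 1 enriched peaks but 0.190% of those of replicate 2, below the pooled background (difference −0.303 to −0.0564 percentage points). For mitochondrial genes the replicate 2 interval included 0 (−0.0169 to 0.249). Protein-coding genes held 85.3% against 89.0%, with an interval that included 0. In genes over 10 kb, 2.49% of reproducible peaks lay within 3 kb of the gene's end against 6.16% of background clusters (difference −4.84 to −2.39 percentage points). This share was 2.43% in replicate 2 but 6.21% in replicate 1, so no difference of replicate 1 from the pooled background was seen. Within 3 kb of the gene's start lay 5.47% of reproducible peaks against 7.10% of background clusters, with an interval that included 0 (−3.70 to 0.78 percentage points). The replicates went opposite ways there, with 11.1% of replicate 1 peaks and 4.37% of replicate 2 peaks.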

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

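Alternatives for the reproducible list, the same-gene draws and the input minimums were chosen after seeing the data, and the others before the data were examined. Both overlap shares stayed above random placement, and the correlation stayed positive and past its threshold, under every alternative run. Counts of enriched peaks moved with the threshold. Replicate 1 had 13113 at log2 fold 2, 2499 at log2 fold 4 and 4727 at −log10 p 5, and replicate 2 had 26266 at log2 fold 2, within 1.5 times its main count, 11052 at log2 fold 4 and 12796 at −log10 p 5. The median fold difference between replicates, 1.36 over all pairs, was 1.08, 0.74 and 0.21 with denominators of at least 2, 5 and 10 in both and turned to −0.12 with at least 15. Merging touching peaks left 945 reproducible sites. With a single replicate, the number of lists past the threshold ranged from 1 to 4: without replicate 2, microRNA, ribosomal protein, mitochondrial and histone genes passed, and without replicate 1 only microRNA genes did. Their cause was not tested. Of 39 list comparisons under alternatives, 34 kept their side of the threshold and their direction where called. No paired analysis was possible because the counts come from the authors' folds and no test across samples. This holds for the counts of enriched peaks only. Each fold already sets IP against the input of the same number. The 2 folds of paired clusters were compared across the replicates by their correlation and by gene-resampled intervals of their median difference. A test of single clusters or genes across the replicates was not run. Planned and not run, for want of sequence and exon annotation here, were gene regions (midpoint rule, stricter p, each replicate alone), Alu overlap (longer match, match nearby, random positions, stricter p, each replicate alone) and folding energy (shorter window, shuffled sequences). Folds at 1 input read are limited by depth, which differed between the replicates.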

Other observations

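The read-floor test and both chromosome 22 tests were set before their values were seen, while the other tests here were chosen or changed afterwards, and all of these patterns were found in the same data. MicroRNA genes were enriched in 52 cases in replicate 1 and 20 in replicate 2, with 7 in both. Of the 52, only 19 had any cluster in replicate 2, so the others could not be scored there. MIR17, MIR18A, MIR19A, MIR20A, MIR19B1 and MIR92A1, all members of the miR-17-92 cluster, were enriched in replicate 1, with log2 folds between 4.50 for MIR17 and 6.60 for MIR19B1. MIR25, MIR93 and MIR106B, a related cluster, reached 4.66, 4.29 and 3.46 there. None of these 9 had a cluster in replicate 2. MIR378A was enriched in both, at 5.15 and 7.19, but 1 other gene span also held its top reproducible peak. Nuclear transfer RNA clusters were enriched in 31 of 147 cases in replicate 1 and 0 of 80 in replicate 2.

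Replicate 2 had more enriched peaks than replicate 1 from fewer clusters. A candidate explanation is the depth of IP relative to input, with a floor of 1 input read. Of 13233 replicate 1 partners of peaks enriched in replicate 2 alone, 6291 (47.5%) sat on the step of 1 input read, between the bounds of 20% and 50% set beforehand. Of all replicate 1 clusters, paired or not, 52.6% sat on that step at any fold, which is not the same measure. The share among the other paired clusters was not computed. Whether the partners sat there more often than like clusters was therefore not tested, and the depth explanation stays open. A higher fold in replicate 2 where the input was well covered was tested in 2 versions: denominators up to 20 gave a median difference of 0.77 (0.69 to 0.86, 2133 pairs), past the bound of 0.5, and denominators up to 200, adopted after that value was seen, gave 0.21 (0.11 to 0.32, 4979 pairs), a value within 0.25 of 0 whose interval passes 0.25 at its upper end. With denominators of at least 15 in both the median was −0.12 (−0.22 to 0.00, 2477 pairs, with 29 enriched in replicate 1 and 33 in replicate 2), so no higher fold in replicate 2 was seen there. The first version goes with a higher fold at well-covered input, the second leaves a small one, and only the minimum of 15, chosen after seeing the data, goes against it, so this stays open. No biological explanation was tested.

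Minus-strand mitochondrial clusters, most of them in ND6, were nearly all enriched. Read abundance may bear on this, since abundant RNA reaches the limit of the p scale. Of 104 plus-strand clusters at the limit, 24 (23.1%) passed log2 fold 3, between the bounds of 20% and 50%, so abundance stays open. After that value was seen, the strands were compared directly: 21 of 21 minus-strand clusters at the limit passed (Fisher's exact p = 1.05e-11). That comparison is only a description, because clusters with fewer reads reach the limit only at higher folds, and no biological explanation was tested.

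Chromosome 22 before BCR, a region picked after its peaks were seen, held 71 reproducible peaks (4.14%) against 0.789% of clusters, in genes that included CDC45, PPIL2, XKR3 and MED15. Of 111 genes, 12 had a reproducible peak, against a mean of 4.40 for random genes with as many clusters. A count above that range was set beforehand as going against more clusters per gene. The choice of region built in such an excess, so the test cannot decide, and more clusters per gene stays open. More reads in IP and input alike could still contribute, since K562 cells are known to carry extra copies near BCR. Among replicate 2 clusters with a denominator of 5 or more, the median log2 fold there was higher by 0.22 (0.05 to 0.58), which neither bound decides. No biological explanation was tested.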
